A study of Homo sapiens with 16 samples.

How the data were processed

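Per the labels, 16 libraries of human monocyte-derived macrophages were made: an m6A immunoprecipitation and an input library for each of 4 genotypes (NTC, METTL3 knockout, WTAP knockout, ZC3H13 knockout) and each of 2 donors, all from cells treated with LPS for 3 h. Per the labels' protocols, total RNA was selected for poly(A) and the 3′ ends of its fragments received adapters carrying barcodes. Per the submitters' processing notes, cutadapt 2.7, STAR 2.6.0c and UMI-tools 0.5.1 were used with the builds hg38 and mm10. The peak caller is not given in the sources used here. Mouse macrophages that the series mentions were not analysed here.

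The authors deposited 1 list of peak segments per immunoprecipitation library, called in that library and not pooled, with coordinates, strand, a −log10 p with a largest value of 400 and a log2 fold of immunoprecipitation over the matched input. The files have no header, so these deposited units were read from the file names and checked on the values. Lists hold enriched and other segments, and a region is often split into many adjacent ones, so the unit here is the segment, not the binding site. The inputs enter only through these values, the libraries hold no read counts, and no depth in reads can be given. The only precision that could be computed for single libraries is the Clopper-Pearson interval of a share of segments, at 95%, which covers counting error and treats neighbouring segments as independent.

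The following choices, except where said otherwise, were made before the data were examined. Segments were enriched at a log2 fold of at least 3 and a −log10 p of at least 3 (p of at most 0.001). The Y chromosome, XIST and TSIX were left out everywhere. Genes were taken from a table of the assembly GRCh38.p14 with 38000 genes and neither strand nor exons. The strand of a gene was therefore inferred, after the files were opened, as the strand of at least 80% of the segments of all 8 libraries whose midpoint lay in that gene alone, with at least 3 such segments. Coding genes with no part of their own took the strand of at least 80% of at least 8 segments that no overlapping gene of known strand could hold. This gave 15518 genes a strand, and the median share of segments on the assigned strand was 100.0%. A segment was given to the gene whose body held its midpoint on the same strand, coding genes first, and to none if several qualified. Of 47861 enriched segments 44139 (92.2%) were given to a gene, 0.1% lay in several genes and 7.7% in none. Without exons and sequence, shares in UTRs, coding sequence and around stop codons, the DRACH motif, and retention by motif were not analysed here. In their place segments within 100 nt of the annotated gene start and within 1000 nt of the annotated gene end were counted, the distances being along the genome. The shares at gene starts and the window at the gene end were chosen after the files were opened.

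Overlaps needed at least 1 nt on the same strand. Cross-donor retention is the share of an NTC library's enriched segments that overlap an enriched segment of the other donor's library of each genotype, NTC being the benchmark. Totals were compared by two-sided exact permutation tests in scipy 1.17.1, where 2 against 2 libraries cannot go below p = 0.33. The number of enriched segments per gene was tested as log2(n + 1) with limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3) in 1 fit of the 8 libraries with a mean per genotype, so that 4 residual degrees of freedom and the spread are shared by all genotypes. The 1583 genes with a mean of at least 1 enriched segment over the 8 libraries were tested. Genes past an adjusted p (Benjamini-Hochberg) of 0.05 in a contrast are said to have fallen or risen, and SE is limma's moderated standard error. With 0 segments in a group the difference depends on the pseudocount of 1 and is no bound. The 13 gene lists were tested with camera in limma at a preset correlation of 0.01 where at least 5 members were tested. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

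The genes named are, per knockout against NTC, the 8 largest falls and the 8 largest rises among those past the threshold and changed in the same direction in both donors (ties by NTC mean, then alphabet). To these come METTL3, WTAP, ZC3H13 and TNF, and from each list up to 3 members with the most enriched segments in NTC. Not every gene that meets this rule is named or drawn. Any other gene named was chosen after its values were seen, which in the between-knockout comparison holds for the genes picked as examples. The replicates are the 2 donors, whose numbers recur in every genotype. Over the 1583 genes the deviations of the donors from the genotype mean correlated by −0.020 to 0.191 between genotypes, so donor as a block was tried as an alternative. In the files read here 0 columns belonged to other series.

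The gene test was checked on simulated data, in which each gene varied by its own spread in the real libraries. The spread in the simulation and the recovery asked of it were set after a first version with other noise had failed. In 5 simulations with 200 changed genes, 0.8% of genes lowered 2-fold and 20.2% of genes lowered 8-fold were called, and 4.55% of calls were unchanged genes. With 900 changed genes 1.96% and 33.9% were called, and 2.42% of calls were unchanged genes. The sign was right in 100% of recovered genes, and 0 genes were called in contrasts with no change. Noise was drawn independently for each gene, with no shift of a whole library, whereas the real libraries differed as a whole. With 900 changed genes a mean of 165 were called, against 981 in the real WTAP knockout. The simulated shares of false calls therefore need not hold for the real contrasts. In these simulations the power of 2 libraries per genotype was low, so a count of 0 or a missing call leaves even large changes open.

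Alternatives tried were a lenient threshold (log2 fold of at least 1), a strict one (log2 fold of at least 4, −log10 p of at least 5), merging within 50 nt, shares of listed segments, reciprocal overlap of 50%, lists reduced to 1893 segments each by −log10 p, any listed segment as target, same-donor retention, donor as a block, scaling by the library's total, fits of only the 4 libraries compared, a pseudocount of 0.5, no filter, bases covered (with a pseudocount of 50), a gene start window of 50 nt in retention, estimated correlation in camera, and each library left out in turn. A further set was chosen after seeing the data. It held merged sites per gene and in retention, the gene-start shares with their 50 nt window and merged sites, leaving out gene-start segments, a log2 fold of at least 3 above the library's own median of mitochondrial segments, and leaving out both ZC3H13 knockout libraries.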

Results

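The m6A mark, a methyl group on adenosines of mRNA, was mapped by m6A-eCLIP in human monocyte-derived macrophages treated with LPS for 3 h. In this assay RNA fragments crosslinked to an m6A antibody are sequenced and compared with a matched input. The 16 samples formed 8 groups of 2 donors each, an immunoprecipitation and an input group for NTC control cells and for knockouts of METTL3, WTAP and ZC3H13. These 3 genes encode members of the complex that writes m6A. The lists deposited for the 8 immunoprecipitation libraries held 162928 to 222042 peak segments each, many of them adjacent pieces of 1 region of hg38, with a p-value and a log2 fold over input that are the authors' own. Their depth in reads is unknown, so intervals below cover the counting of segments only. A segment was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3.

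The first comparison asks how much of the m6A signal of stimulated macrophages depends on each knocked-out gene. The WTAP knockout libraries had 1893 and 1987 enriched segments (1940 ± 66.5, mean ± SD, n = 2 donors), against 10392 and 8402 in NTC (9397 ± 1407). Within donors this was 0.209 ± 0.038 of the NTC number (SD, n = 2). The METTL3 knockout had 7680 and 6530 (7105 ± 813), which was 0.758 ± 0.027 of NTC, and both libraries lay below both NTC libraries. The ZC3H13 knockout had 7622 in donor 1 and 3355 in donor 2 (5488.5 ± 3017), or 0.733 and 0.399 of NTC. Enriched segments were shorter in the WTAP knockout, with a median of 18 and 20 nt against 44 and 53 nt in NTC. Counted as enriched bases, the WTAP knockout held 0.109 ± 0.014 of NTC and the METTL3 knockout 0.735 ± 0.020. The ZC3H13 knockout held 0.716 in donor 1 and 0.357 in donor 2. Genes with at least 1 enriched segment numbered 3298 and 3016 in NTC, 2556 and 2431 in the METTL3 knockout, 991 and 1053 in the WTAP knockout, and 2515 and 1479 in the ZC3H13 knockout. Of all listed segments, 5.64% (95% Clopper-Pearson interval 5.54 to 5.75) and 5.16% (5.05 to 5.27) were enriched in NTC, against 0.933% (0.892 to 0.976) and 0.895% (0.856 to 0.935) in the WTAP knockout. The two-sided exact permutation p was 0.33 for each knockout, the smallest that 2 against 2 libraries allow.

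Segments of the mitochondrially encoded transcripts served as a background measured in the same libraries, and 0 of 3920 were enriched. Their median log2 fold was −0.22 and −0.18 in NTC, 0.21 and 0.31 in the METTL3 knockout, 0.75 and 0.79 in the WTAP knockout, and −0.38 and 0.38 in the ZC3H13 knockout. With enrichment counted from 3 above each library's own mitochondrial median, a cutoff chosen after seeing the data, the METTL3 knockout held 0.347 ± 0.019 of the NTC number and the WTAP knockout 0.0369 ± 0.0058. The ZC3H13 knockout held 0.931 of it in donor 1 and 0.133 in donor 2. The ratio in the WTAP knockout was 0.454 with the lenient threshold (log2 fold of at least 1) and 0.344 with the strict one (at least 4), and that in the ZC3H13 knockout was 0.883 with the lenient threshold. In the METTL3 knockout it was 0.875 ± 0.008 with the lenient threshold and 0.970 ± 0.145 with the strict one, where donor 1 had 0.867 and donor 2 had 1.07 of NTC.

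**Figure D1:**
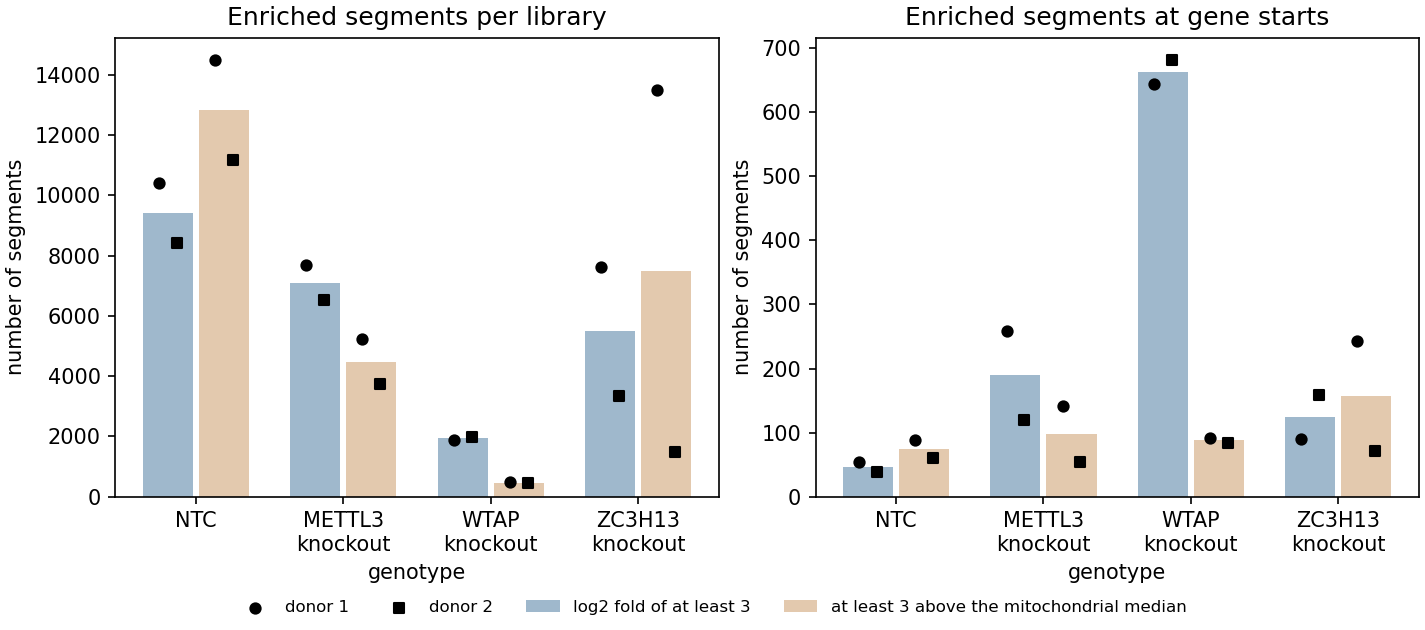
Number of enriched segments per library (left) and of those within 100 nt of an annotated gene start (right), with bars at the mean of both donors and points for single libraries, for the planned cutoff and for the cutoff above the mitochondrial median. Both WTAP knockout libraries, at 1893 and 1987 segments in all, lie below the others on the left and, at 644 and 682 gene-start segments, above them on the right with the planned cutoff.

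To ask which positions of the NTC pattern were still marked, enriched NTC segments were looked up in libraries of the other donor, with an overlap of at least 1 nt on the same strand. In NTC cells of the other donor 66.7% ± 5.2 (SD, n = 2) of the segments were found again. The WTAP knockout kept 2.09% ± 0.08, a difference from NTC of −64.6 percentage points ± 5.2. The METTL3 knockout kept 51.1% ± 0.78, a difference of −15.5 points ± 4.4 with both donors below NTC. The ZC3H13 knockout kept 25.4% in donor 2 and 57.2% in donor 1, a difference of −25.3 points ± 17.3. Between the donors of 1 genotype the share of segments found again, averaged over both directions, was 66.7% in NTC, 60.9% in the METTL3 knockout, 51.2% in the WTAP knockout and 46.6% in the ZC3H13 knockout. After merging neighbouring segments, 2651 sites were enriched in both NTC libraries, and of these 1260 were enriched in both METTL3 knockout libraries, 738 in both ZC3H13 knockout libraries and 51 in both WTAP knockout libraries. Among these 51 are the 39 sites enriched in all 8 libraries, most of them narrow, for which short shared fragments are a candidate explanation (see the other observations). The difference for METTL3 was −40.3 points with the cutoff above the mitochondrial median, and −2.00 points with the strict threshold, where 1 donor was at −8.75 and the other at 4.76. Counting any listed segment of the target library, enriched or not, left −2.26 points for METTL3, −25.7 for WTAP and −1.72 for ZC3H13.

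**Figure D2:**
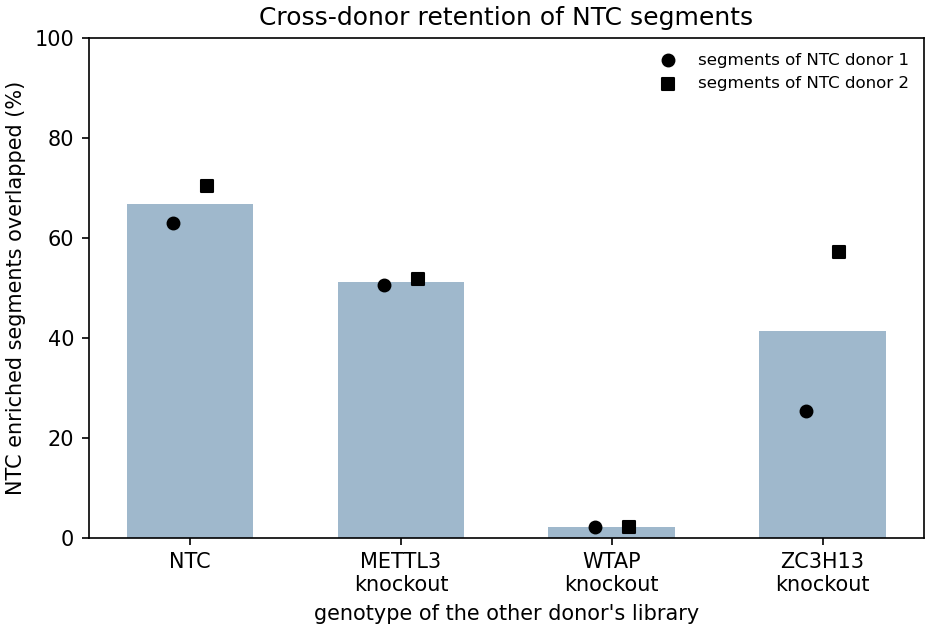
Percent of the enriched segments of each NTC library that overlapped an enriched segment in the other donor's library of each genotype, with bars at the mean and points for the NTC donor whose segments were looked up. The WTAP knockout kept 2.15% and 2.03%, against 63.0% and 70.3% in NTC.

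Positions along the gene were compared because m6A antibodies also bind m6Am, a mark next to the mRNA cap that another enzyme makes. Among enriched segments given to a gene, 39.0% ± 0.36 (SD, n = 2) lay within 100 nt of the annotated gene start in the WTAP knockout, against 0.533% ± 0.050 in NTC and 2.81% ± 1.17 in the METTL3 knockout. In the ZC3H13 knockout the share was 1.27% in donor 1 and 5.34% in donor 2. The gene-start segments numbered 644 and 682 in the WTAP knockout, 55 and 39 in NTC, 259 and 120 in the METTL3 knockout, and 90 and 159 in the ZC3H13 knockout. The 55 and 39 NTC segments at gene starts were found again in 43.8% ± 7.5 of cases in the WTAP knockout and 25.4% ± 7.6 in NTC. NTC segments elsewhere in genes were found again in 1.69% ± 0.03 in the WTAP knockout and 68.0% ± 5.1 in NTC. Segments within 1000 nt of the annotated gene end, where m6A of mRNA is dense, made up 19.2% and 18.0% of enriched segments in NTC, 16.7% and 17.6% in the METTL3 knockout, 3.13% and 3.74% in the WTAP knockout, and 20.7% and 16.1% in the ZC3H13 knockout. Of NTC segments near the gene end, 72.6% ± 5.9 were found again in NTC, 53.7% ± 2.1 in the METTL3 knockout, 1.19% ± 0.32 in the WTAP knockout, and 46.0% ± 27.5 in the ZC3H13 knockout. Of the WTAP knockout's gene-start segments 84.5% and 86.8% were also listed in NTC of the other donor, but 2.48% and 3.96% were enriched there. With the cutoff above the mitochondrial median the gene-start segments numbered 92 and 84 in the WTAP knockout, 89 and 60 in NTC, 142 and 54 in the METTL3 knockout and 243 and 72 in the ZC3H13 knockout. Their mean share was then 22.4% in the WTAP knockout and 0.616% in NTC, 2.25% in the METTL3 and 3.76% in the ZC3H13 knockout.

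The transcript of TNF, a cytokine induced by LPS and of particular interest in this study, was compared segment by segment (chromosome 6, 31575565 to 31578336, plus strand). Both NTC libraries listed 19 enriched segments between 31577604 and 31577769, in the last part of the gene. The METTL3 knockout had 20 and 13, the WTAP knockout 0 and 0, and the ZC3H13 knockout 7 and 0. The strongest segment, 31577669 to 31577676, had a deposited log2 fold of 4.21 and 4.13 in NTC and 4.18 and 4.27 in the METTL3 knockout. The mitochondrial medians of these libraries were −0.22 and −0.18 in NTC and 0.21 and 0.31 in the METTL3 knockout. Similar deposited folds therefore lay less far above that background in the METTL3 knockout. In the ZC3H13 knockout the strongest segment, from 31577670, had 3.22 and 2.95. In the WTAP knockout the segments that begin at 31577669 had 0.40 and 0.90, while segments at the gene start had up to 2.17 and 2.44. By limma, the number of TNF segments fell in the WTAP knockout (log2(n + 1) difference −4.32 ± 0.91 SE, adjusted p = 0.0123). Neither the METTL3 knockout (−0.22 ± 0.91, adjusted p = 0.982) nor the ZC3H13 knockout (−2.82 ± 0.91, adjusted p = 0.190) passed the test in limma. With the cutoff above the mitochondrial median the limma differences were −0.45 (METTL3, adjusted p = 0.798), −4.46 (WTAP, adjusted p = 0.0440) and −2.67 (ZC3H13, adjusted p = 0.510).

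**Figure D3:**
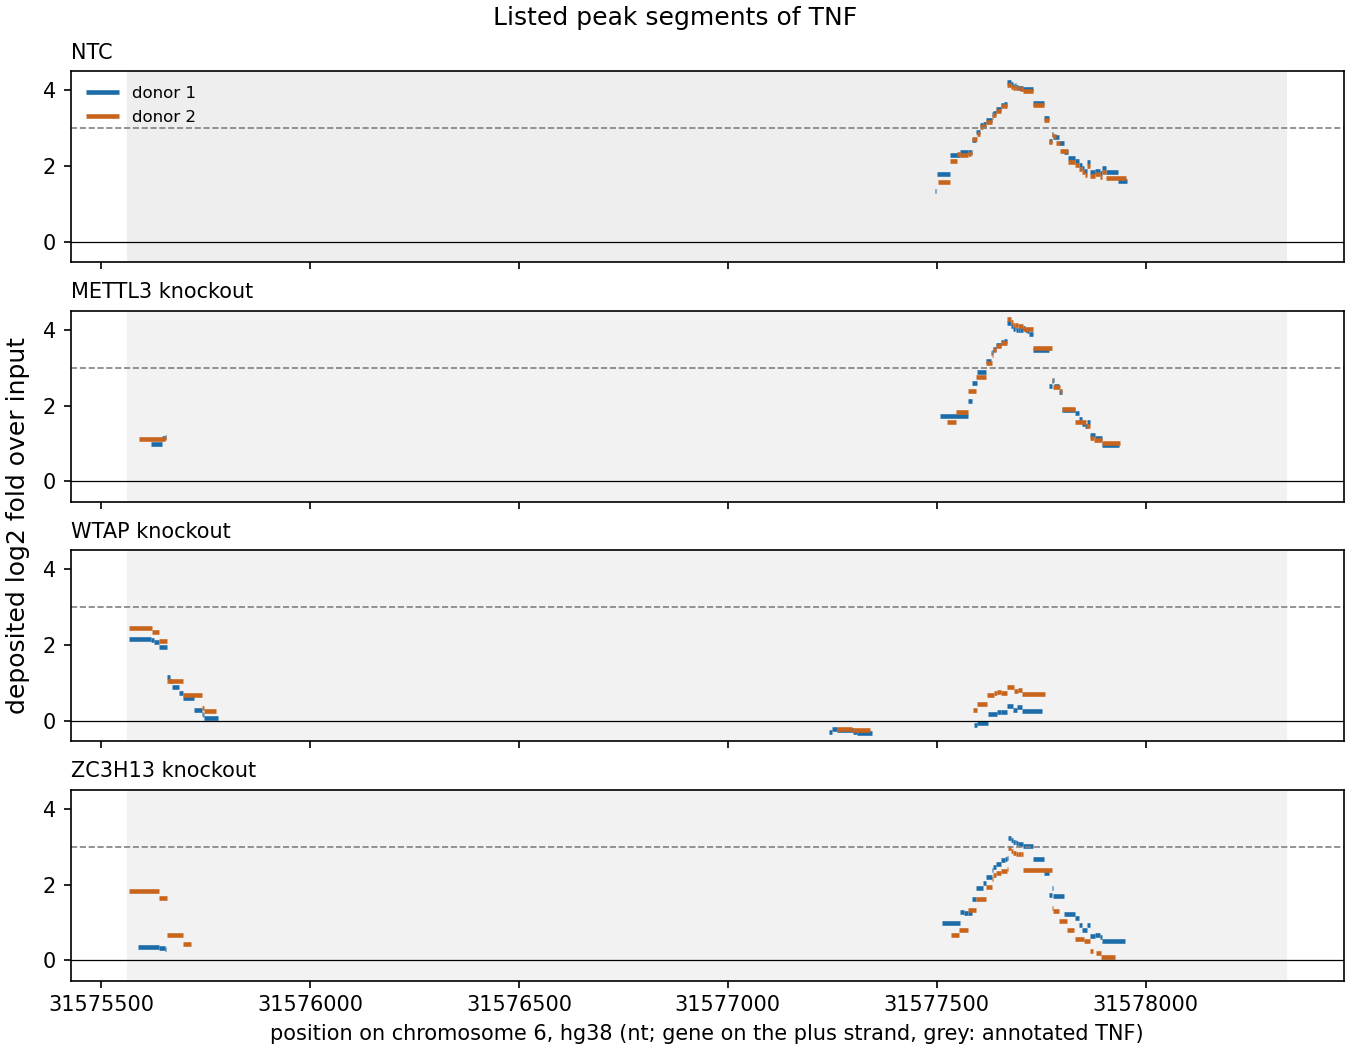
Listed peak segments of TNF in each genotype, with the position on chromosome 6 on the x axis, the deposited log2 fold over input on the y axis, the enrichment cutoff of 3 dashed and the gene in grey. The 19 enriched segments of each NTC library lie between 31577604 and 31577769, where the WTAP knockout has 0.

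Gene by gene, the WTAP knockout had the largest number of changes. limma tested 1583 genes, and in 931 the number of enriched segments fell and in 50 it rose. ICAM1, an adhesion molecule gene, had 28 and 28 segments in NTC and 0 in both WTAP knockout libraries (log2(n + 1) difference −4.86 ± 0.49 SE, limma adjusted p = 0.00254). The ATP receptor gene P2RX7 had 30 and 27 in NTC and 0 and 0 (−4.88 ± 0.84, limma adjusted p = 0.00753), and TRAF1, a signalling adaptor gene of the TNF receptor family, had 25 and 25 and 0 and 0 (−4.70 ± 0.28, limma adjusted p = 0.00115). TNFAIP8, JUN, TNC, DUSP1 and TRIB1 completed the 8 largest falls, each from a mean of 22 to 27 segments in NTC to 0, with differences of −4.81 to −4.50. Of the 931 genes 849 (91.2%) had 0 enriched segments in both WTAP knockout libraries. The 8 largest rises, in ARHGDIA, DPM3, CFD, PFDN4, TST, VPS28, CAPZA1 and CARHSP1, went from 0 in both NTC libraries to 4 to 7 segments, with differences of 2.56 to 2.90. In ARHGDIA 4 and 3 of the 6 and 7 segments lay at the gene start, while in TST and VPS28 0 did. With the cutoff above the mitochondrial median the differences were 0.5 in ARHGDIA, CFD and TST and 1 in VPS28, and the other 4 were not tested. Over all genes 1 rose and 894 fell with that cutoff, 683 of them among the 931. Of the 50 genes that rose 12 were tested with that cutoff, the others having too few segments left. Without gene-start segments 22 genes rose. The total of a library counts enriched segments, so scaling by it divides out a loss shared by many genes. What remains are changes relative to the library. Scaling each library by its total moved the median of all genes from −1.79 to −1.21 in the WTAP knockout, from −0.25 to 0.02 in the METTL3 knockout and from −0.68 to −0.15 in the ZC3H13 knockout. It gave 609 falls and 143 rises (19.0% of calls, against 5.10%) in the WTAP knockout, where the 8 largest falls still passed, with adjusted p = 0.0012 to 0.0340 in limma. Counts depended on single libraries: 313 genes fell and 29 rose without NTC donor 1, 473 and 30 without NTC donor 2, 164 and 2 without WTAP knockout donor 1, and 177 and 3 without WTAP knockout donor 2.

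Lists of genes fixed beforehand were followed in the same fits, to see whether the inflammatory transcripts of stimulated macrophages shared in the loss. Of all 1583 tested genes 931 fell and 50 rose in the WTAP knockout. A majority of falls within a list is therefore not by itself particular to that list. In the WTAP knockout 5 of 6 tested genes for cytokines and chemokines fell (TNF, CSF1, TNFSF10, TNFSF15 and IFNB1), and 1 rose, with the same counts adjusted over the list alone. The gene that rose was IL1A, which had 0 segments in NTC and 4 and 6 in the WTAP knockout (2.56 ± 0.26 SE, limma adjusted p = 0.00263). All of them lay at the gene start, and 0 passed the cutoff above the mitochondrial median (TNFSF10, TNFSF15 and IL1A were named after their values were seen). For NF-kB and TLR signalling 12 of 14 tested genes fell and 0 rose, over all genes and adjusted over the list alone, among them TLR2 (18 and 22 in NTC, 0 and 0) and CD14 (20 and 14 in NTC, 2 and 1). The interferon response had 6 falls among 10 tested genes by both counts, including IFIT2 (16 and 16 in NTC, 0 and 1), SOCS3 and IFIT3. Of 18 immediate-early and AP-1 transcription factor genes 14 fell, and adjusted over the list alone 14 fell and 1 rose. JUN had 30 and 24 in NTC and HIVEP2 16 and 14, both against 0 and 0. Of 7 genes for mRNA decay and AU-rich element binding 5 fell (6 adjusted over the list alone), including ZFP36L2, BTG1 and ZC3H12A. Of 9 MAPK phosphatase and signalling regulator genes 5 fell by both counts, including DUSP1, GADD45B and DUSP6.

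All 4 tested macrophage marker genes fell in the WTAP knockout, over all genes and adjusted over the list alone. Among them were VSIG4, which had 21 and 15 segments in NTC and 0 and 0 in the WTAP knockout, and CEBPA (9 and 10, against 1 and 1). IL7R, the 1 tested gene of the lymphocyte, neutrophil, platelet and erythroid markers, is also expressed by stimulated monocytes and fell from 22 and 20 to 0 and 0 by both counts. CD2 and FCGR3B of that list had at most 1 enriched segment in any library. The m6A reader genes YTHDF2 (6 and 5 in NTC) and YTHDF3 (9 and 3) both fell to 0 and 0 by both counts, and YTHDF1 had 2 and 1 and was not tested. Of 3 long noncoding RNAs MALAT1 fell (3 and 5 in NTC, 0 and 0), and adjusted over the list alone 2 fell and 1 rose. WTAP and RBM15, the 2 tested genes of the writer complex, did not pass by either count. Enriched segments were seen in 3 of 54 ribosomal protein genes and 0 of 15 mitochondrially encoded genes, and none of either list was tested. As sets against all other genes, the 6 lists with at least 5 tested members gave 0 calls by camera in limma, with NF-kB and TLR signalling lowest (unadjusted p = 0.0222, adjusted p = 0.133 and adjusted p = 0.898 with an estimated correlation). That list was called with the cutoff above the mitochondrial median (adjusted p = 0.0254) and without WTAP knockout donor 1, where 1 list was called. Among the named list members, scaling by the total, which divides out a shared loss, ended the calls of IFNB1 (adjusted p = 0.214), CD14 (0.106), CEBPA (0.199) and TNFSF15 (0.0615) in limma. The differences shrank from −2.56 ± 0.83 to −1.23 ± 0.82 SE for IFNB1, from −2.86 ± 0.80 to −1.01 ± 0.49 for CD14 and from −2.39 ± 0.67 to −0.70 ± 0.45 for CEBPA, and less for TNFSF15, from −2.82 ± 0.97 to −2.09 ± 0.81. The cutoff above the mitochondrial median ended those of CD14 (adjusted p = 0.0617), ZC3H12A (0.0571) and TNFSF15 (0.0515), and left IL1A untested. Their differences grew with that cutoff, and so did the SE: from −2.86 ± 0.80 to −4.52 ± 1.81 for CD14, from −2.73 ± 0.88 to −3.23 ± 1.24 for ZC3H12A, and from −2.82 ± 0.97 to −3.35 ± 1.21 for TNFSF15. With donor as a block TNFSF15 did not pass either (adjusted p = 0.0590). The block left 4 falls among the cytokine and chemokine genes and 13 among the transcription factor genes, and gave 6 each for mRNA decay and for the MAPK regulators.

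**Figure D4:**
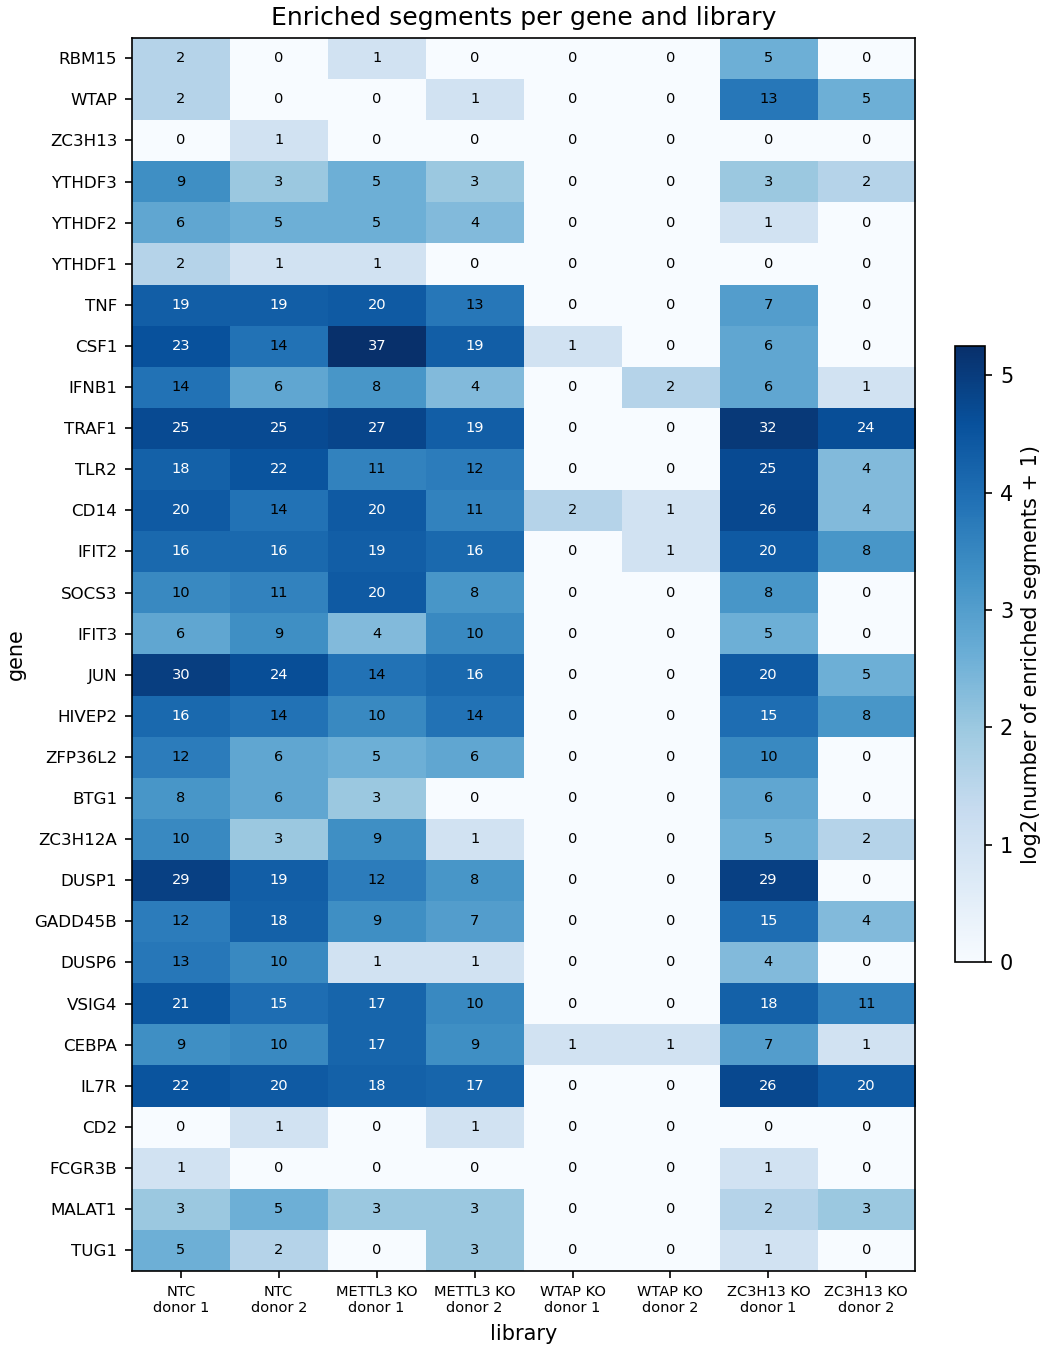
Number of enriched segments per library for up to 3 of the genes of each list with the most enriched segments in NTC, with libraries on the x axis, genes on the y axis and colour for log2(number + 1). WTAP knockout columns hold 0 for most genes, such as TRAF1 with 25 and 25 in NTC, while TRAF1 has 27 and 19 in the METTL3 knockout and 32 and 24 in the ZC3H13 knockout.

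In the METTL3 knockout 6 genes fell and 1 rose by limma, while 143 were lower and 40 higher at an unadjusted p under 0.05. HSPA5, which encodes a chaperone of the endoplasmic reticulum, had 6 and 7 enriched segments in NTC and 0 in the 6 knockout libraries (METTL3 difference −2.90 ± 0.25 SE, limma adjusted p = 0.0210). CSGALNACT2 (4 and 5 in NTC), SMIM15 (4 and 4), ARHGAP25 (5 and 3), KIAA0040 (3 and 5) and MBD5 (3 and 3) also fell to 0 and 0, with differences of −2.45 to −2.00. In all 6 genes the donors had equal numbers within each knockout, so only the NTC pair could add to their spread in the shared fit. Passing thus did not follow the size of the fall alone. DUSP6, with 13 and 10 in NTC and 1 and 1 in the METTL3 knockout, did not pass (−2.63 ± 0.73, limma adjusted p = 0.306). VPS28 rose from 0 and 0 to 4 and 5 (2.45 ± 0.30, limma adjusted p = 0.0414). Among inflammatory transcripts ICAM1 had 32 and 18, CD14 20 and 11, and IFIT2 19 and 16. JUN had 14 and 16, against 30 and 24 in NTC, and TLR2 11 and 12, against 18 and 22. None of these passed. Differences were negative in 16 of 18 tested immediate-early, 11 of 14 NF-kB and TLR, 5 of 10 interferon and 4 of 6 cytokine genes. Their medians were −0.80, −0.48, −0.06 and −0.40, against −0.25 over all genes. KLF6, named after its values were seen, had 9 and 4 in NTC and 0 and 0 in the METTL3 knockout (−2.82 ± 0.48, limma adjusted p = 0.116). No list member passed over all genes. Adjusted over the list alone 1 immediate-early gene was lower and 1 long noncoding RNA higher. By camera 0 of 6 lists were called, with adjusted p = 0.565 as the lowest and adjusted p = 0.908 with an estimated correlation. With donor as a block limma gave 0 falls and 0 rises, with adjusted p = 0.0836 to 0.144 for the 7 genes called in the main fit. Scaling by the total and the cutoff above the mitochondrial median each gave 0 and 0 as well. At an unadjusted p under 0.05 the block had 139 genes lower and 45 higher, scaling 70 and 46, and that cutoff 372 and 2. With that cutoff the 6 falls had larger differences but also larger SE (HSPA5 −3.52 ± 1.13, CSGALNACT2 −3.00 ± 0.52), while the rise of VPS28 shrank to 0.37 ± 1.09. With scaling the 6 falls had differences of −2.15 to −1.37 and VPS28 2.05. Without both ZC3H13 knockout libraries, a setting chosen after seeing the data, 91 genes fell and 20 rose, and with the cutoff above the mitochondrial median as well 634 fell and 6 rose. Without ZC3H13 knockout donor 1 or donor 2 alone 51 fell and 10 rose, or 63 and 10. Without METTL3 knockout donor 2 the counts were 10 and 5, and without METTL3 knockout donor 1 or any 1 NTC or WTAP knockout library 0 and 0. At an unadjusted p under 0.05 these last fits had 90 to 126 genes lower and 23 to 33 higher, except without NTC donor 1, where 38 were lower and 63 higher. The lenient threshold gave 0 falls and 2 rises, with 670 genes lower and 490 higher at an unadjusted p under 0.05, and the strict one 0 and 0, with 3 and 12.

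In the ZC3H13 knockout 12 genes fell and 0 rose by limma, while 270 were lower and 15 higher at an unadjusted p under 0.05. The glycosyltransferase gene GALNT6 had 7 and 9 enriched segments in NTC and 0 and 0 in the ZC3H13 knockout (−3.16 ± 0.30 SE, limma adjusted p = 0.0162), with 5 and 6 in the METTL3 knockout. HSPA5 fell likewise (−2.90 ± 0.25, limma adjusted p = 0.0162). TMEM250 (6 and 5 in NTC), C14orf119 (5 and 4), CSGALNACT2, DIPK1A (4 and 4), SMIM15 and ARHGAP25 completed the 8 largest falls, all to 0 and 0, with differences of −2.70 to −2.29. These 8 genes also had 0 and 0 in the WTAP knockout, so neither that genotype nor the ZC3H13 knockout could add to their spread in the shared fit. The transcript of WTAP had 13 and 5 enriched segments in the ZC3H13 knockout against 2 and 0 in NTC, which did not pass over all genes (2.40 ± 0.71, limma adjusted p = 0.167) but made 1 rise in the writer complex adjusted over the list alone. With the cutoff above the mitochondrial median this difference was −0.08 ± 1.04 (limma adjusted p = 0.978). The transcript of WTAP had 0 and 0 in the WTAP knockout. METTL3 had 0 in NTC and in the WTAP knockout, and 2 and 0 in both the METTL3 and the ZC3H13 knockout. ZC3H13 had 0 and 1 in NTC and 0 in all knockouts. Such numbers say nothing on the level of the transcripts or on the knockout itself. YTHDF2, with 1 and 0, was 1 lower reader gene adjusted over the list alone, and 0 members of any list passed over all genes. camera called 0 of 6 lists, with adjusted p = 0.906 as the lowest and adjusted p = 0.987 with an estimated correlation. With donor as a block limma gave 0 falls and 0 rises, with adjusted p = 0.0627 to 0.108 for these 8 genes. Scaling by the total, the lenient threshold and the cutoff above the mitochondrial median also gave 0 and 0. At an unadjusted p under 0.05 scaling had 134 genes lower and 63 higher, the lenient threshold 430 and 383, that cutoff 156 and 2, and the block 280 and 17. The 8 genes had differences of −2.38 to −1.61 with scaling, and of −2.56 to −1.58 with SE of 0.45 to 1.13 with the cutoff above the mitochondrial median. Left-out libraries gave 454 falls and 21 rises without ZC3H13 knockout donor 1, 25 and 4 without donor 2, 33 and 3 or 37 and 4 without METTL3 knockout donor 1 or 2, and 0 and 0 without any 1 NTC or WTAP knockout library (102 to 227 genes lower and 14 to 31 higher at an unadjusted p under 0.05).

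Differences between the knockouts were tested directly, since the members of the complex need not be equally required. Between the WTAP and METTL3 knockouts 571 genes differed by limma, 549 with fewer segments in the WTAP knockout and 22 with more. TNF, ICAM1 and TRAF1 were among those with fewer in the WTAP knockout, with differences of −4.10 ± 0.91 SE (adjusted p = 0.0191), −4.65 ± 0.49 (adjusted p = 0.00307) and −4.56 ± 0.28 (adjusted p = 0.000868). Between the ZC3H13 and WTAP knockouts 323 genes differed, 301 with more segments in the ZC3H13 knockout and 22 with fewer. ICAM1 had 36 and 14 segments in the ZC3H13 knockout (4.56 ± 0.49, limma adjusted p = 0.00405) and TRAF1 had 32 and 24 (4.84 ± 0.28, limma adjusted p = 0.00136), whereas TNF with 7 and 0 did not pass (1.5 ± 0.91, limma adjusted p = 0.338). The transcript of WTAP also had more segments in the ZC3H13 than in the WTAP knockout (3.20 ± 0.71, limma adjusted p = 0.0262). Between the ZC3H13 and METTL3 knockouts 0 genes differed by limma, with 187 lower and 33 higher at an unadjusted p under 0.05. Neither TNF (−2.60 ± 0.91, limma adjusted p = 0.303) nor CSF1 (6 and 0, against 37 and 19 in the METTL3 knockout, −3.38 ± 0.95, limma adjusted p = 0.224) passed there. With the cutoff above the mitochondrial median 0 genes differed in each of the 3 contrasts, with 317, 319 and 50 at an unadjusted p under 0.05 for WTAP against METTL3, ZC3H13 against WTAP and ZC3H13 against METTL3. For ZC3H13 against METTL3 the direction of these unadjusted differences turned: 11 were lower and 39 higher with that cutoff, and 225 and 337 with the lenient threshold. Scaling by the total changed the share of calls with more segments from 3.85% to 20.8% for WTAP against METTL3 and from 93.2% to 79.1% for ZC3H13 against WTAP (644 and 560 genes). Single libraries mattered here too: for WTAP against METTL3 the count was 327 and 355 without METTL3 knockout donor 1 and 2, 52 and 55 without WTAP knockout donor 1 and 2, and 873 and 864 without ZC3H13 knockout donor 1 and 2. For ZC3H13 against WTAP it was 7 and 11 without WTAP knockout donor 1 and 2, and 751 without ZC3H13 knockout donor 2. For ZC3H13 against METTL3, 283 genes were lower and 20 higher without ZC3H13 knockout donor 1, but 12 lower and 24 higher without donor 2.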

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

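All the settings with a cutoff above the mitochondrial median, the settings without both ZC3H13 knockout libraries and both tests of the donor difference in the ZC3H13 knockout were chosen after the results were seen.

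The WTAP knockout differed from each of the other knockouts with the planned cutoff, while no gene was called between the ZC3H13 and METTL3 knockouts. limma called 571 genes whose numbers of enriched segments differed between the WTAP and METTL3 knockouts, 549 of them lower in the WTAP knockout, with TRAF1 at 0 and 0 segments against 27 and 19. It called 323 genes that differed between the ZC3H13 and WTAP knockouts, 301 of them higher in the ZC3H13 knockout, where TRAF1 had 32 and 24. Both counts come from tests of the difference itself. The first was 52 without WTAP knockout donor 1, 55 without WTAP knockout donor 2, 327 and 355 without METTL3 knockout donor 1 and 2, and 873 and 864 without ZC3H13 knockout donor 1 and 2. The second was 7 without WTAP knockout donor 1, 11 without WTAP knockout donor 2 and 751 without ZC3H13 knockout donor 2. With the cutoff above the mitochondrial median both counts were 0, with 317 and 319 genes at an unadjusted p under 0.05 in limma. That cutoff left 13499 enriched segments in donor 1 and 1489 in donor 2 of the ZC3H13 knockout, a spread that 1 fit shares with every genotype. Without both ZC3H13 knockout libraries the same cutoff gave 554 genes between the WTAP and METTL3 knockouts, 548 of them lower in the WTAP knockout. A library-wide shift of the deposited folds, as far as mitochondrial segments measure it, is argued against as the source of the lower library totals in the WTAP than in the METTL3 knockout. Mitochondrial medians were 0.75 and 0.79 in the WTAP and 0.21 and 0.31 in the METTL3 knockout, and a higher median lets more segments pass a fixed cutoff. Counting from the median moved the ratios to NTC from 0.209 to 0.0369 (SD 0.0058) in the WTAP and from 0.758 to 0.347 (SD 0.019) in the METTL3 knockout, so the gap of the totals in relative terms widened. Other measures kept their direction but narrowed. The median gene difference, WTAP minus METTL3, went from −1.5 to −1. Retention went from 2.09% and 51.1% to 1.165% and 30.4%, a smaller gap in points. Without both ZC3H13 knockout libraries 879 genes differed with the planned cutoff, against the 554 above. A different need for the 3 genes and a different degree of knockout stay open, as untested.

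The ZC3H13 knockout had fewer enriched segments in donor 2 than in donor 1, which enters the 323 genes above. A donor difference shared by all genotypes would put the ratio of donor 2 over donor 1 inside the range of the other 3 genotypes. With the planned cutoff the ratio was 0.4402 in the ZC3H13 knockout, outside their 0.809 to 1.05. These ratios had been seen when the comparison was chosen, so it describes the pattern and is no independent test. The ratio was likewise lower than in the other 3 with the strict threshold (0.378, against 0.691 to 0.972) and with the cutoff above the mitochondrial median (0.110, against 0.713 to 0.964). With the lenient threshold it was 0.874, inside their 0.857 to 1.08, so the drop particular to this knockout was not seen there. A weaker immunoprecipitation of every class in donor 2 may have contributed but stays open. Gene-start segments in donor 2 over donor 1 were 0.2963 (95% interval 0.225 to 0.387) with the cutoff above the mitochondrial median and 1.77 (1.36 to 2.31) with the planned cutoff, so the class that a weaker immunoprecipitation should lower was lower with 1 cutoff and higher with the other. A different degree of knockout in the 2 donors was not tested, since neither protein nor transcript levels were used here, and stays open as the biological explanation.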

How the results depend on the processing

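Of 195 alternative values for 36 results, leaving out single libraries aside, 78 kept the outcome. Counts of genes and lists and ratios to NTC could not be labelled as reversed. The absence of that label among all 305 values therefore says little. Directions did turn in some counts at an unadjusted p under 0.05 in limma. Between the ZC3H13 and METTL3 knockouts 187 genes were lower and 33 higher in the main fit, but 225 and 337 with the lenient threshold. In the METTL3 knockout 6 genes fell and 1 rose in the main fit, and 0 fell and 2 rose with the lenient threshold. The unadjusted counts there, 670 lower and 490 higher, kept the direction of the main fit (143 and 40). Chosen after seeing the data were the merged sites (except in the totals), the gene-start shares with their 50 nt window, leaving out gene-start segments, the cutoff above the mitochondrial median, and leaving out both ZC3H13 knockout libraries. The lenient and strict thresholds and the left-out libraries tried on those shares were planned for shares by transcript region, which the gene-start shares replaced. Unless a sentence names one, the cause was not tested. Values in a series are in the order METTL3, WTAP, ZC3H13 knockout.

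The number of genes lower in the WTAP knockout (931) stayed within 846 and 1348 in 9 settings: donor as a block, the 4 libraries alone, a pseudocount of 0.5, no filter, covered bases, no gene-start segments, the cutoff above the mitochondrial median, and no ZC3H13 knockout libraries with either cutoff. These 9 are listed because their counts came out near 931. From 520 (no filter) to 927 (no gene-start segments) of the 931 genes were lower in them too. The count was 3709 with the lenient threshold, 609 with scaling, 342 with merged sites and 16 with the strict threshold.

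The lenient threshold gave ratios of enriched segments to NTC of 0.875, 0.454 and 0.883, and retention differences of −10.1 points (METTL3) and −76.0 (WTAP). Retention was 93.8%, 96.0% and 92.3% at gene starts and 79.6%, 9.92% and 79.6% elsewhere. Gene-start shares were 4.63% in NTC and 10.6%, 33.4% and 10%. TNF had a mean of 43.5 segments in NTC and 33.5, 5 and 24. Those of the WTAP knockout, 6 and 4, all lay between 31575566 and 31575695, in the first part of the gene. Where the NTC segments were enriched with the planned cutoff, its log2 folds reached at most 0.40 and 0.90. The METTL3 knockout had 0 genes lower and 2 higher, the WTAP knockout 3709 and 775, and the ZC3H13 knockout 0 lower, over 8225 genes instead of 1583. WTAP against METTL3 gave 3384 genes and ZC3H13 against WTAP 3399. In the WTAP knockout 4 lists were called: immediate-early genes and MAPK regulators lower, ribosomal proteins and mitochondrially encoded genes higher.

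The strict threshold gave ratios of 0.970 (METTL3) and 0.344 (WTAP), retention differences of −2.00 and −28.7 points, retention of 8.33% and 16.7% at gene starts and 36.1% and 7.98% elsewhere, and gene-start shares of 0.402% in NTC and 17.8% in the WTAP knockout. TNF had 7.5 segments in NTC and 6 in the METTL3 knockout. With 132 genes left to test, 0 were lower and 0 higher in the METTL3 knockout, 16 and 2 in the WTAP knockout, and 1 lower in the ZC3H13 knockout. WTAP against METTL3 gave 20 genes, ZC3H13 against METTL3 1, and ZC3H13 against WTAP 6.

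The cutoff above the mitochondrial median gave ratios of 0.347 (METTL3) and 0.0369 (WTAP), a retention difference of −40.3 points for METTL3, and gene-start shares of 0.616% in NTC and 22.4% in the WTAP knockout. In the METTL3 knockout 0 genes were lower and 0 higher, in the WTAP knockout 1 was higher, and in the ZC3H13 knockout 0 were lower. WTAP against METTL3 gave 0 and ZC3H13 against WTAP 0. The NF-kB and TLR list, 1 of 7 tested, was called in the WTAP knockout. Without the ZC3H13 knockout libraries 91 genes were lower and 20 higher in the METTL3 knockout, with 879 for WTAP against METTL3. With that cutoff as well, 634 were lower and 6 higher in the METTL3 knockout and 5 higher in the WTAP knockout.

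Merging within 50 nt gave a WTAP ratio of 0.280, and the share of listed segments 0.169. Reciprocal overlap of 50% left 48.8%, 42.3% and 38.9% shared between donors in NTC, METTL3 and WTAP knockouts, and a WTAP retention difference of −47.3 points. Any listed segment as target left differences of −2.26, −25.7 and −1.72 points, equal numbers of segments −74.0 for WTAP, and merged sites −53.6 for WTAP. Merged sites gave gene-start shares of 0.936% in NTC, 4.42% (METTL3) and 39.95% (WTAP), and, over 718 genes, 19 genes lower and 11 higher in the METTL3 knockout, 342 and 6 in the WTAP knockout, and 32 and 4 in the ZC3H13 knockout. A gene start window of 50 nt gave WTAP retention of 52.6% at gene starts and 1.75% elsewhere, and shares of 0.324% in NTC and 28.0% in the WTAP knockout.

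Donor as a block gave 0 genes lower and 0 higher in the METTL3 knockout and 0 lower in the ZC3H13 knockout, with adjusted p for the named genes of 0.0627 to 0.144. Scaling by the total gave 0 lower and 0 higher (METTL3), 609 and 143 (WTAP), 0 lower (ZC3H13), and 560 for ZC3H13 against WTAP. The 4 libraries alone gave 70 lower and 6 higher (METTL3), 111 higher (WTAP), and 68 and 5 (ZC3H13). A pseudocount of 0.5 gave 20 and 1 (ZC3H13). No filter, with 5883 genes tested, gave 226 and 45 (METTL3), 169 higher (WTAP), and 278 and 21 (ZC3H13). Where limma called 0 genes in both directions, the genes lower and higher at an unadjusted p under 0.05 were as follows, against 143 and 40 (METTL3) and 270 and 15 (ZC3H13) in the main fit. Donor as a block gave 139 and 45 (METTL3) and 280 and 17 (ZC3H13), scaling 70 and 46 and 134 and 63, and the cutoff above the mitochondrial median 372 and 2 and 156 and 2. The strict threshold gave 3 and 12 (METTL3), the other way round from the main fit, and the lenient threshold 430 and 383 (ZC3H13). Covered bases gave 10 and 0 (METTL3), and 83 and 2 (ZC3H13). Leaving out gene-start segments gave 3 and 0 (METTL3) and 22 higher (WTAP).

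With 1 library left out, the lone library of a genotype being assumed to vary like the others, ratios ranged from 0.739 to 0.777, 0.182 to 0.236 and 0.399 to 0.733. Gene-start shares ranged from 0.497% to 0.568% in NTC and 1.98% to 3.64%, 38.7% to 39.2% and 1.27% to 5.34%. Genes lower in the METTL3 knockout numbered 0 to 63 and higher 0 to 10, lower in the WTAP knockout 164 (without its donor 1) to 1058 (without ZC3H13 knockout donor 2) and higher 2 to 64, and lower in the ZC3H13 knockout 0 to 454 (without its donor 1) and higher 0 to 21. WTAP against METTL3 ranged from 52 to 873, ZC3H13 against METTL3 from 0 to 303, and ZC3H13 against WTAP from 7 to 751. Lists called were 0 to 0, 0 to 1 and 0 to 0. Fewer libraries leave fewer degrees of freedom, which alone lowers counts.

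The strict threshold left no list with 5 tested members. Stop codon windows of 100 and 400 nt, shares in exon regions, the DRACH and GGACT settings and retention by motif were not run, for want of exons and sequence. Depth in reads is unknown, so its limit on weak segments was not measured. The simulated data give the limit of the gene test only for noise that is independent between genes.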

Other observations

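The test of short fragments at sites enriched in all 8 libraries was chosen after the result was seen, as were MAT2A and the cutoff above the mitochondrial median; the other tests here were written before their results were seen, on patterns noticed in the data.

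The WTAP knockout had more enriched segments at gene starts than NTC, 644 and 682 against 55 and 39. A hypothesis is that the deposited log2 folds of a library shift as a whole, so that a fixed cutoff lets more gene-start segments pass where little other m6A is left. Mitochondrial segments, which are not enriched in any library, had medians of 0.75 and 0.79 in the WTAP knockout and −0.22 and −0.18 in NTC. The gap between gene-start and mitochondrial medians differed between the WTAP knockout and NTC by −0.1792 in donor 1 and 0.011 in donor 2, within the 0.5 set for such a shift. Counted from the mitochondrial median, gene-start segments in the WTAP knockout over NTC were 1.034 in donor 1 and 1.40 in donor 2. Both values are consistent with a library-wide shift as the source of the excess, and the shift itself could arise when loss of m6A leaves a larger share of the immunoprecipitated reads to other fragments. Other gene starts were listed in the WTAP knockout: genes with a listed start numbered 7732 and 8045 there and 5820 and 5629 in NTC. Starts listed in both libraries of a donor numbered 5362 and 5273. Of the enriched gene-start segments of the WTAP knockout, however, 84.5% and 86.8% were also listed in NTC of the other donor. Most of them were thus not newly listed. Among starts listed in both libraries, 44.93% in donor 1 and 62.1% in donor 2 had the higher gap in the WTAP knockout, which left that test undecided. A rise of m6Am at these starts is therefore not needed to explain the counts, and a small one in donor 2 is not excluded.

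At 39 merged sites a segment was enriched in all 8 libraries, the WTAP knockout included. If these were m6A sites that need none of the 3 genes, other NTC segments of the same transcripts should lie near them as often as near other sites. Such a neighbour within 500 nt was listed for 25.64% of the 39 sites, against 90% of 500 other sites enriched in both NTC libraries, which argues against this for the set. Of the 39 sites 74.36% were under 35 nt wide, against 1.95% of 2612 other sites, and the median width was 26 nt against 201 nt. Short fragments shared between the libraries, for example from handling or sequencing in common, are therefore a candidate explanation for most of them. The 10 wider sites, 6 of them with a neighbour, may hold others. ERG, ROBO2 and MAML3, named after their values were seen, hold sites of the narrow kind.

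MAT2A, whose transcript is methylated by an enzyme outside the complex studied here, had 4 enriched segments in donor 1 of the WTAP knockout and 0 in the other 7 libraries. With the lenient threshold it had 7 of 14 listed segments in donor 1 and 4 of 10 in donor 2 of NTC, 13 of 13 and 15 of 15 in the WTAP knockout, 15 of 16 and 14 of 14 in the METTL3 knockout, and 12 of 15 and 18 of 18 in the ZC3H13 knockout. With the cutoff above the mitochondrial median it had 0 in all 8 libraries, NTC included, so that count cannot compare the genotypes. Its strongest segment lay 2.03 and 1.70 above the mitochondrial median in NTC. The values were 2.32 and 1.92 in the METTL3 knockout, 2.86 and 2.12 in the WTAP knockout, and 2.67 and 2.13 in the ZC3H13 knockout. In donor 1 of the METTL3 knockout the strongest segment lay at 85543813 to 85543821. In the other 7 libraries it lay between 85544967 and 85545143, so that 1 value belongs to another position. By the strongest segment, wherever it lay, each knockout was above NTC in both donors, a difference that was not tested.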
